A study of Mus musculus with 2 samples.

How the data were processed

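Single-cell RNA libraries of CD45-positive cells from subcutaneous MC38 tumours were compared, 1 control library and 1 PBM library. Per the labels, tumours were taken on day 14, digested for 20 min with 1 mg/mL collagenase IV and 50 U/mL DNase, passed through a 70 µm strainer, sorted for CD45 and pooled within a condition; the number of mice in a pool is not stated there. The deposited matrices hold raw UMI counts per gene and cell barcode, with no normalization. Per the labels, libraries were made with a 10x Genomics 3′ kit of version 3.1, sequenced on a NovaSeq and processed with Cell Ranger 7.2.0 against mm10. The matrix headers name another program, PISA 0.12, and the barcodes carry cell numbers followed by an N number from 1 to 9 in place of a nucleotide sequence; 50.8% of control and 49.6% of PBM barcodes have N equal to 1. Which program made the matrices and filtered the barcodes is therefore not settled. The kit named in the labels could not be checked from these files either. Every barcode held more than 1000 UMIs (the lowest totals were 1002 and 1005), and every listed gene was seen in at least 1 cell. The feature lists hold 26394 and 23277 symbols, of which 22483 are in both. A gene listed for 1 library only was left out of the clustering and of the ranking of genes. It could enter list medians and random lists, with no UMI in the other library.

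The 2 libraries form 2 groups of 1, so cells were not treated as replicates, no test was made and no genes were called. Group names were taken from the labels, and the comparison was PBM against control throughout. Total UMIs, medians per barcode and cell numbers open the results; the median number of genes per barcode was 1727 and 1489.5. Cells needed at least 500 UMIs, at least 200 genes and at most 10% mitochondrial UMIs, which removed 11 of 11238 control barcodes and 1 of 13962 PBM barcodes. Doublets were called per library with Scrublet in scanpy 1.11.5, at an expected rate of 0.8% per 1000 barcodes and the automatic threshold. This removed 128 control and 899 PBM barcodes, 1.14% and 6.44% of those tested, against expected rates of 8.98% and 11.2%.

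Counts of genes in both lists were scaled to 10000 per cell and log-transformed, and 2000 variable genes were chosen with the library as batch key after mitochondrial, ribosomal protein, cell cycle and antigen receptor segment genes were left out. Clusters came from 30 principal components, 15 neighbours and Leiden clustering (igraph 0.11.9) at resolution 1.0 with seed 0, without integration. T cells, monocytes and macrophages, and dendritic cells were re-clustered with 20 components. The re-clustered T cells include a cluster of 429 control and 808 PBM cells led by Ly6c2, Cxcr3 and Cd160. Its leading class was T cell, but more markers of another class stood among its 10 leading genes. It therefore stayed unnamed and is not among the T-like cells. Clusters were named from marker sets of 14 classes and 10 subtypes. A cluster took the class with the largest share of its markers met, at 1.5 times the mean CPM over clusters and in 10% of the cluster's cells. Cells whose cluster took the fibroblast class by this rule are called Sparc-led here, after a leading gene. It stayed unnamed with under 3 such markers, with more markers of another class than of its own among its 10 leading genes, or with none of its own there and a median UMI count under 0.3333 of its library's median. Leading genes were ranked by fold with 1 CPM added, among genes in 25% of the cluster's cells. The values of 1 CPM and 25% were set after the clusters had been seen: with a minimum of 10% the cluster of control T cells led by Ifng and Pdcd1 would have stayed unnamed.

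Shares of cells have exact (Clopper-Pearson) 95% intervals. Levels are summed UMIs of a class in a library per 1000000 of that class's total, with exact Poisson 95% intervals, and log2 ratios have exact conditional binomial intervals. Classes with at least 100 cells in each library were compared, which gave 4. No subtype reached that number in both, so gene levels were not read by subtype. The largest monocyte cluster of the PBM library, read alone as an alternative, had 83 PBM cells and did not reach it either. A sum of 0 was set to the floor of 3 counts in that library's class, and a list member whose level in the other library lies below this floor was counted neither as higher nor as lower. For each of 37 gene lists the median log2 ratio over members with at least 20 UMIs was taken, with its 95% range over 1000 Poisson resamples of the sums and its place among 10000 random lists matched on mean expression in 20 bins. Markers that define a class were left out of that class's lists. All these intervals cover counting error only.

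The genes named are the 5 with the largest log2 ratio in each direction per class, or 10 for monocyte/macrophage-like cells and CD8 T cells, among genes with at least 100 UMIs, 50 CPM in either library and intervals that do not overlap. Ribosomal, mitochondrial, antigen receptor, haemoglobin, sex-linked, unnamed gene-model and class marker genes were left out of this ranking. Up to 4 members of a described list with the largest absolute ratio and at least 100 UMIs, and a set of immune genes fixed with the rule, could be named as well. Only some of the genes this rule allows are printed; those were picked after their values were seen, and so were genes named as leaders of a cluster. A few genes the rule allows are not reported one by one and are left out of the counts of gene ratios, but they stay members of their lists. CD8 T cells were taken by UMIs, since no CD8 sub-cluster had enough cells in both libraries.

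The filters, clustering settings, marker sets, gene lists, rule for naming and most alternatives were fixed before the data were examined. Of the 148 pairs of a list and a class that were computed, 84 are described, those in which the list is about genes of that class. This assignment was made after the medians were seen. In the 64 pairs not described, 39 of 656 values under alternatives had the sign opposite to the value reported, against 61 of 893 in those described; in 17 and 23 of these the interval of the value reported excluded 0. Free RNA was estimated after the data were seen. The estimate is the median, over other classes' markers of at least 100 CPM, of the level in a class relative to the whole library. Doublets left in and true expression of these markers would raise it.

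Alternatives were no UMI or mitochondrial limit, doublets kept, Leiden resolutions 0.5 and 2.0, each library clustered on its own, cells thinned to 1000 UMIs, trimmed mean of M values (TMM) factors from edgeR 4.0.16, the mean of each cell's CPM, other minimum counts for list members, and T cells split by UMIs. Alternatives added after the data were seen were free RNA subtracted, T cells gated on Cd8a or Cd8b1 or on Cd4, the largest monocyte cluster of the PBM library alone, shares without the Sparc-led and low-count clusters, unnamed clusters given to their leading class, T-like cells with the Ly6c2-led cluster or without the Ifng-led one, the B-like cluster with most control cells alone, the interferon-led clusters left out, and the ranking of genes limited to those of which free RNA could supply under 50%. The ratios were tested on simulated data with known folds of 4, 2, 0.5 and 0.25 in 50 genes each: the median log2 ratios were 2.00, 1.00, -1.02 and -2.01, and the 95% intervals held the true value in 100%, 92%, 98% and 94% of genes. For the 9429 genes simulated without a difference the intervals held it in 95.5%. The simulated sums were Poisson counts of the whole control profile, and the genes scored had at least 100 expected UMIs. Such data follow the model of the intervals, so they check the calculation only. They do not cover the smaller and unequal sums of single classes, such as 579823 PBM and 51677710 control UMIs in monocyte/macrophage-like cells. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and anndata 0.12.19, and R 4.3.3.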

Results

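Single-cell RNA sequencing was carried out on CD45-positive cells, the immune fraction, sorted from subcutaneous tumours of MC38, a mouse colon carcinoma line, grown in C57BL/6 mice. The control and PBM groups held 1 library each, made from cells pooled within a condition. PBM is photobiomodulation, a treatment with light that began on day 7 and was given daily until the tumours were taken on day 14. The control library held 11238 barcodes with 104673228 unique molecular identifiers (UMIs) and a median of 5622 UMIs per barcode, and the PBM library held 13962 barcodes with 86159897 UMIs and a median of 5144. After filtering and doublet removal, 11099 control cells and 13062 PBM cells were compared. With 1 library per group there is no replicate error: every interval given is a 95% interval that covers counting error only, no test was made, and the treatment, the pool of animals and the library cannot be told apart. Genes are named by symbol, the only identifier the feature lists hold, and levels are counts per 1000000 UMIs (CPM) of a cell class.

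The series title states the aim of altering the immune cells of the tumour and restoring T cell immunity, so the comparison asks which immune cells each library held. The control library consisted mainly of myeloid cells and the PBM library of lymphocytes. Cells with monocyte and macrophage markers made up 46.0% of the control library (45.0 to 46.9) and 1.35% of the PBM library (1.16 to 1.56). Cells with B cell markers made up 1.86% (1.61 to 2.13) and 42.8% (41.9 to 43.6), and cells with T cell markers 19.6% (18.9 to 20.4) and 46.9% (46.1 to 47.8). Natural killer (NK) cells, identified by genes such as Ncr1 and Klrb1c, made up 12.0% of the control library (11.4 to 12.6) and 1.51% of the PBM library (1.31 to 1.73).

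In percentage points, PBM minus control, the differences were -44.60 for monocyte/macrophage-like cells, 40.9 for B-like cells, 27.3 for T-like cells and -10.49 for NK-like cells. Dendritic-like cells, led by Ccl22, Il12b and Fscn1, numbered 157 in the control library (1.42%, 1.20 to 1.65) and 4 in the PBM library (0.031%, 0.008 to 0.078), and 436 (3.93%) and 76 (0.582%) at resolution 2.0. Neutrophil-like cells, led by S100a8, S100a9 and Retnlg, numbered 72 (0.649%, 0.508 to 0.816) and 12 (0.092%, 0.047 to 0.160). A cluster led by Sparc, Col1a2 and Dcn, genes of extracellular matrix and connective tissue that a CD45 gate is meant to leave out, held 10.9% of the control library (10.4 to 11.5) and 0.054% of the PBM library (0.022 to 0.110). Clusters left unnamed held 7.56% and 7.28%, among them the Ly6c2-led cluster, whose leading class was T cell. With Leiden resolution 0.5 the T-like difference was 45.9 points: 1478 control and 90 PBM T-like cells were then in clusters that met no class, and 13 control and 802 PBM cells without a class at resolution 1.0 became T-like. With each library clustered on its own the monocyte/macrophage-like difference was -29.32 points.

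**Figure D1:**
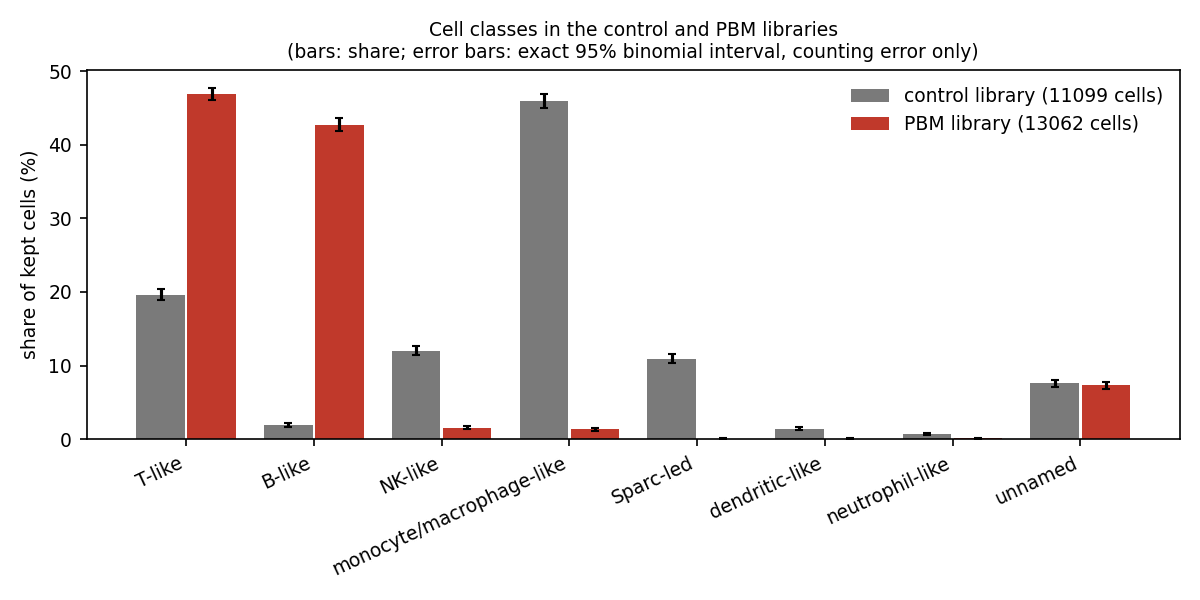
Share of kept cells (%, vertical axis) in each cell class for the control library (grey) and the PBM library (red), with exact 95% binomial intervals as error bars. Monocyte/macrophage-like cells held 46.0% of the control library, and T-like and B-like cells held 46.9% and 42.8% of the PBM library.

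The T-like cells of the libraries lay in different clusters. In the control library 50.7% of T-like cells (48.6 to 52.8) were in a cluster led by Ifng, which encodes interferon gamma, Ccl4, Ccl3, and the checkpoint receptor genes Pdcd1 and Lag3, and this cluster held 0.277% of the T-like cells of the PBM library (0.162 to 0.444). Of the PBM library's T-like cells, 2539 were in a cluster led by Dapl1, Ccr9 and Cd8b1, where the control library had 26, and 2506 were in a cluster led by Cd40lg, Cd4 and Lef1, where it had 58. When T cells were re-clustered, sub-clusters with naive-like markers (such as Ccr7, Lef1 and Tcf7) held 1.38% of control (0.969 to 1.91) and 54.1% of PBM T cells (52.9 to 55.3). They held 1.04% and 40.4% at resolution 0.5, 3.99% and 31.8% at resolution 2.0, and 4.76% and 48.5% with doublets kept. Sub-clusters meeting the CD8 T cell list, which holds effector genes such as Nkg7, Ccl5 and Gzmk, held 74.5% (72.8 to 76.2) and 0.807% (0.610 to 1.05). Their shares were 74.7% and 8.97% at resolution 0.5, 57.6% and 0.505% at resolution 2.0, and 71.3% and 3.15% with doublets kept.

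That last contrast does not measure how many T cells carried CD8. Counted by UMIs of Cd8a or Cd8b1 without Cd4 in cells thinned to 1000 UMIs, CD8-positive cells made up 37.0% of control T cells (35.2 to 38.9) and 41.5% of PBM T cells (40.3 to 42.7), a difference of 4.47 points. Its direction cannot be read, because such counts have a background in other classes that rose by more. The same gate took 2.91% of control and 8.97% of PBM B-like cells, at a median of 2677 and 4447 UMIs per cell before thinning, and 2.33% and 17.0% of monocyte/macrophage-like cells, at 7015 and 2210. Cd4-positive cells without Cd8 made up 11.2% and 8.002%, while sub-clusters of conventional CD4 type had given 0.422% and 10.8%, though 13.6% and 6.88% at resolution 2.0 and none with doublets kept. Cells with a UMI of Foxp3, the master regulator of regulatory T cells, made up 12.0% (10.8 to 13.3) and 2.61% (2.25 to 3.01), against 21.8% and 0.101% in sub-clusters meeting the regulatory T cell list. The Foxp3 count took no control and 0.197% of PBM B-like cells, and 0.373% and 1.14% of monocyte/macrophage-like cells. The Cd4 count took no control and 0.949% of PBM B-like cells, and 0.529% and 2.84% of monocyte/macrophage-like cells. Before re-clustering, a cluster led by Izumo1r, Tbc1d4 and Foxp3 held 676 PBM and 23 control cells, so most of its PBM cells lay outside the sub-clusters meeting the regulatory list, which held 7 PBM cells. At resolution 2.0 those sub-clusters held 22.1% and 7.08%, with 491 PBM cells. Gamma-delta or innate-like sub-clusters held 1.27% and 0.995% of T cells, and 0.575% and 33.3% met no subtype.

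T-like cells of the PBM library had far lower levels of effector and checkpoint genes and higher levels of naive and stem-like genes. All 17 measured members of the cytotoxicity list were lower in the PBM library, with a median log2 ratio of -3.78 (-3.99 to -3.58). Gzmb, the gene of the killing enzyme granzyme B, stood at 964 CPM in control and 28.1 in PBM T-like cells (log2 -5.10, -5.19 to -5.01), Prf1 (perforin) at 317 and 46.7, and Ifng at 446 and 9.02. Of the 15 exhaustion genes 14 were lower, with a median of -4.08 (-4.31 to -3.79). The checkpoint receptor genes Pdcd1 (168 and 5.98 CPM), Lag3 (91.9 and 2.05) and Havcr2 (88.0 and 1.66) were among them, as were Rgs16 (log2 -5.77) and Bhlhe40 (-4.98), while Tox stood at 56.6 and 80.0. Of the 15 memory and stem-like genes 13 were higher in the PBM library, with a median of 1.83 (1.76 to 1.90), among them Tcf7 (65.6 and 471 CPM), the transcription factor of naive and stem-like T cells, Lef1 (50.0 and 395) and Id3 (5.57 and 96.4). Xcl1, a chemokine gene on the same list, went the other way (881 and 23.1 CPM).

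**Figure D2:**
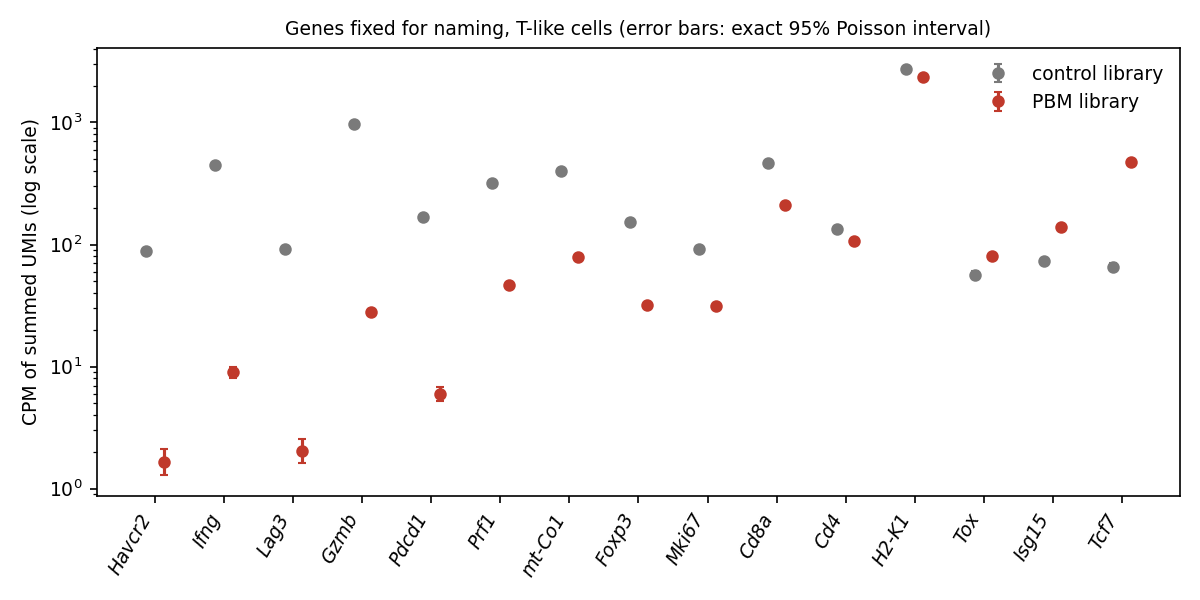
Level in T-like cells (CPM of summed UMIs, log axis) of 15 genes in the control library (grey) and the PBM library (red), with exact 95% Poisson intervals that are mostly smaller than the points. Gzmb, Ifng, Pdcd1, Lag3 and Havcr2 lie lower in the PBM library and Tcf7 lies higher; H2-K1, close between the libraries, takes the other sign with TMM factors.

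Genes of activation and suppression went with the effector genes. Of 14 activation and costimulation genes 12 were lower in PBM T-like cells (median -2.01), with Tnfrsf9 at 800 and 25.7 CPM, Tnfrsf4 at 709 and 73.4, Il2ra at 218 and 26.8, and Tnfsf9 at a log2 ratio of -3.88. All 15 members of the regulatory T cell programme were lower (median -3.14), with Ccr8 at -4.33, Entpd1 at -4.08 and Klrg1 at -3.44. Foxp3 itself stood at 154 and 31.7 CPM. Over all alternatives the median of this programme ranged from -4.83 to -2.59. All 17 NF-kB and inflammatory genes were lower (median -1.76), led by the chemokine genes Ccl4 (2363 and 24.7 CPM) and Ccl3 (703 and 7.47). Cd8a stood at 468 and 212 CPM and Cd4 at 135 and 107. The T cell receptor signalling genes had a median of -0.17, close to the median of all genes in these cells (-0.19), and Zap70 (-0.89) and Prkcq (0.55) differed in sign. The cytotoxicity median was -1.83 with the T-like class from Leiden resolution 0.5, and -2.01 without the Ifng-led cluster, an alternative added after the data were seen.

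Metabolic and growth genes of T-like cells were lower in the PBM library. Of 18 glycolysis genes 17 were lower (median -1.88), with the lactate exporter gene Slc16a3 at 88.7 and 2.65 CPM, Hk2 at 41.8 and 2.82, Tpi1 at 458 and 48.7, and the glucose transporter gene Slc2a1 at 59.6 and 11.7. Of 16 hypoxia genes 14 were lower (median -1.51), with Bnip3 at -3.65 and Hif1a at -2.70. All 22 S phase genes and 26 of 27 genes of the G2 and M phases were lower (medians -1.06 and -1.32); the proliferation gene Mki67 stood at 92.8 and 31.4 CPM. Cholesterol synthesis genes were lower in 15 of 16 cases (median -1.42), and immediate early genes in 13 of 16 (median -1.02). Interferon-gamma response genes were lower in 21 of 25 cases (median -0.61), below the range of random lists matched on expression (-0.48 to 0.04), and had -1.29 without the Ifng-led cluster, -1.03 in CD4-gated and -0.20 in CD8-gated cells. NRF2 target (-0.56) and apoptosis genes (-0.54) lay just below their ranges, and TGF-beta pathway (-0.50), MHC class I (-0.44) and heat shock genes (-0.40) inside them. Without the Ifng-led cluster the medians were -1.05 for TGF-beta, -0.95 for NRF2, -0.77 for MHC class I, -0.71 for apoptosis and -0.50 for heat shock genes. Over all alternatives the lowest and highest medians were -1.51 and -0.20 for interferon-gamma response, -1.37 and -0.02 for TGF-beta, and -1.09 and -0.25 for NRF2 genes. They were -0.87 and -0.13 for MHC class I, -0.77 and -0.23 for apoptosis and -0.57 and -0.10 for heat shock genes. For the S phase they were -1.31 and -0.75, and for the G2 and M phases -1.48 and -0.79. H2-K1 stood at 2761 and 2344 CPM and was higher in the PBM library with TMM factors (log2 0.07).

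Among all genes passing the rule for naming, those with the largest ratios in T-like cells were Ccl1 (332 and 0.124 CPM), Gzmf (356 and 0.865), Gzmd (74.2 and 0.272), Spp1 (274 and 1.81) and Pf4 (89.7 and 0.618), higher in the control library, and Cd79a (2.15 and 170), Fcmr (1.11 and 78.7), Ms4a1 (0.891 and 52.6), Ly6d (2.08 and 111) and Dapl1 (25.7 and 573), higher in the PBM library. Spp1 and Pf4 are macrophage genes and Cd79a, Fcmr, Ms4a1 and Ly6d are B cell genes. Free RNA could supply 82.9% of the Spp1 level in control T-like cells, and 85.8% or more of the levels of the B cell genes in PBM T-like cells. Free RNA in T-like cells was estimated at 13.1% of the library level in the control and 17.2% in the PBM library. Single markers behind this estimate ranged from 7.82% to 177% in the control and from 10.7% to 83.4% in the PBM library. Limited, after the data were seen, to genes of which free RNA could supply under 50%, the ranking added Ccl4 and Ccl3 on the control side and Id3, Atp1b1 (3.34 and 55.0 CPM), Rflnb (18.3 and 201) and Treml2 (7.199 and 76.0) on the PBM side.

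T cells gated on CD8 showed the same contrast, though the gate also takes cells by background. Among cells with a Cd8a or Cd8b1 UMI and no Cd4 UMI (966 control and 2879 PBM cells), a gate added after the data were seen, Ifng stood at 482 and 2.68 CPM, Gzmb at 821 and 11.8, Pdcd1 at 222 and 3.01, and Tcf7 at 61.6 and 425. Ccl1 stood at 558 CPM in the control library against 1 UMI in the PBM library (log2 -13.54, -18.84 to -11.06). Other genes with the largest ratios were Gzmf (376 CPM and 17 PBM UMIs), Nrgn (362 and 1.32), Ccl3 (763 and 3.01) and Gzmc (215 and 1.46) on the control side, and Tmem108 (3.08 and 57.4), Dapl1 (44.6 and 654), Id3 (7.18 and 101) and Rflnb (14.2 and 165) on the PBM side. The same ranking also held Mt2, Mt1, Ccl9 and C1qb on the control side, of which free RNA could supply 53.6% or more in that library, and Fcmr, Ly6d, Ms4a1, Cd79a, H2-Ob and Cd79b on the PBM side, of which it could supply 66.1% or more. Below 50%, Ccl4, Tubb6, Gzmd and Rgs16 took the open places on the control side, and genes such as Dtx1, Pik3ip1, Rtp4, Treml2 and Nsg2 on the PBM side.

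The B-like cells of the libraries also lay in different clusters. A cluster led by Igkc, Mzb1 and Pou2af1 held 136 of 206 control and 167 of 5587 PBM B-like cells, and another held 49 control and 4572 PBM cells, so the class values compare different clusters. Over the class, B-like cells of the PBM library had higher levels of type I interferon response genes and lower levels of activation genes. Of 24 type I interferon response genes 22 were higher in the PBM library, with a median of 1.39 (1.09 to 1.60), and the other 2 had no control UMI and a PBM level below the floor of 3 counts, so they cannot be placed. The transcription factor gene Irf7 stood at 17.6 and 69.4 CPM and Isg15 at 12.8 and 55.2. The members with the largest ratios, Usp18, Ifit1, Oas3 and Ifit2, rested on 1 UMI each in the 206 control cells (Usp18 log2 3.36, 0.88 to 8.67). Of 17 activation and germinal centre genes 13 were lower and 1 could not be placed (median -1.15, -1.36 to -0.82), with Cd69, an early activation marker, at 275 and 69.1 CPM, Ccr7 at 462 and 145, and Myc at 120 and 45.3. All 16 immediate early genes were lower (median -1.39), with Jun at 278 and 47.0, Fos at 379 and 118, and Rhob at 73.5 and 7.86. Within the Igkc-led cluster alone, read after the data were seen, the type I interferon median was 0.62 (0.34 to 1.16; 9 of 10 genes higher), inside the range of random lists matched on expression (-0.58 to 0.63). The activation median there was -0.26 (-0.62 to 0.30) and the immediate early median -2.50 (-2.75 to -2.08). Over the whole B-like class Mef2b, a germinal centre gene of the activation list, went the other way (log2 2.49, 0.63 to 5.54, on 2 control UMIs).

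The MHC class I median of B-like cells was 0.38, with 12 of 16 genes higher in the PBM library, against a median of -0.24 over all genes. For MHC class II 8 of 13 genes were higher, and the median of 0.17 lay inside the range of matched random lists (-0.27 to 0.21). Within the Igkc-led cluster alone the medians were 0.10 and -0.80. H2-K1 stood at 1674 and 2154 CPM. Medians below that of all genes were those of cholesterol synthesis (-0.78), hypoxia (-0.71), NRF2 targets (-0.66), the G2 and M phases (-0.62), glycolysis (-0.57), heat shock (-0.37) and apoptosis (-0.33), and the interferon-gamma response (-0.02) and S phase (-0.15) medians lay above it. The G2 and M phase, heat shock, apoptosis, interferon-gamma response and S phase medians lay inside the ranges of matched random lists. After free RNA was subtracted the glycolysis median was 0.06 and that of the G2 and M phases -1.38, and in thinned cells the heat shock and apoptosis medians were 0.15 and 0.03. Over all alternatives the lowest and highest medians were -0.98 and -0.40 for cholesterol synthesis, -1.12 and -0.28 for hypoxia, and -0.69 and -0.17 for NRF2 targets. They were -0.33 and 0.26 for the interferon-gamma response, 0.10 and 0.66 for MHC class I and -0.80 and 0.45 for MHC class II. Within the Igkc-led cluster alone the heat shock (0.54), apoptosis (0.52), S phase (1.90) and G2 and M phase (1.55) medians were above 0. The largest ratios in B-like cells belonged to Arg1 (382 and 3.79 CPM), C1qb, Ccl6, Mt1 and Spp1 on the control side, genes with high levels in macrophages of which free RNA could supply 99.4% or more in that library, and to Tcf7, Cd8b1, Ly6c2, Isg15 and Irf7 on the PBM side, where it could supply 88.3% of the Tcf7 and all of the Cd8b1 level. Under 50% the ranking gave Rhob, Jun, Cebpb (136 and 23.3), Tsc22d3 (428 and 79.9) and Pim1 (165 and 33.5), and, on the PBM side, also Ublcp1 (16.0 and 52.1) and Slfn5 (27.2 and 80.3). Mki67 rested on 5 control UMIs (log2 -0.60, -1.85 to 1.05), so no difference was detectable at this depth.

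NK-like cells lay in a single cluster in both libraries (1332 and 197 cells), with a lower level of several granzymes and of proliferation genes in the PBM library. Of 16 cytotoxicity genes 13 were lower (median -0.59, -0.76 to -0.50). Gzmc stood at 6463 and 208 CPM, Gzmd at 985 and 5.50, Gzmg at 411 and 8.80 and Gzme at 369 and 22.003, while Gzmb (1099 and 503) and Prf1 (1350 and 847) differed less and Ifng was higher (58.7 and 97.9). Of 27 genes of the G2 and M phases 25 were lower (median -1.61), and of 22 S phase genes 21 (median -1.28). In cells thinned to 1000 UMIs these medians were -0.69 on 8 genes and -0.77 on 11. Mki67 stood at 46.2 and 16.5 CPM. Of 20 type I interferon response genes 18 were higher in the PBM library (median 0.86, 0.71 to 1.17), with Rtp4 at 9.80 and 55.0, Irf7 at 21.5 and 74.8 and Oas1a at 12.2 and 29.7; Ifi27l2a had a log2 ratio of 2.82, but free RNA could supply 82.0% or more of it in both libraries.

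Other NK-like medians were -1.53 for cholesterol synthesis, -1.39 for hypoxia, -1.20 for glycolysis, -0.64 for NRF2 targets, -0.60 for heat shock and 0.24 for MHC class I, against 0.08 over all genes; the interferon-gamma response (0.07), apoptosis (-0.09) and immediate early (-0.09) medians had intervals that included 0. The lowest and highest values over all alternatives were -2.68 and -0.70 for cholesterol synthesis, -1.57 and -0.77 for hypoxia, and -1.38 and -0.91 for glycolysis. They were -0.82 and -0.13 for NRF2 targets, -0.78 and -0.27 for heat shock, 0.06 and 0.26 for MHC class I and -0.40 and 0.33 for immediate early genes. The genes with the largest ratios were Gzmd, Arg1, Ccl6, Fn1 and C1qb on the control side and Dapl1, Cd79a, Cd79b, Ly6d and Cd8b1 on the PBM side. All but Gzmd are genes of other classes, of which free RNA could supply 58.7% or more in the library where they were higher. With those left out the ranking gave Adam8, Gzmg, Ifitm2 (743 and 19.8 CPM) and Gzmc, and on the PBM side Acp5 (10.5 and 64.9), Cmah (10.0 and 61.6), S1pr5 (13.8 and 83.6), a receptor for exit from tissue, Tspan32 (12.5 and 71.5) and Rtp4. Adam8 had 601 control UMIs and 1 PBM UMI (log2 -5.82, -11.12 to -3.33).

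The 176 monocyte/macrophage-like cells of the PBM library differed from the control cells in their sub-clusters. Sub-clusters with macrophage markers held 35.6% of the 5100 control cells (34.3 to 37.0) and 2.84% of the PBM cells (0.929 to 6.51), and sub-clusters with monocyte markers 32.0% and 54.5% (46.9 to 62.1), the rest meeting no subtype; the monocyte difference was 22.5 points, but -2.47 at resolution 2.0. Genes with lower levels in the PBM library, among those fixed for naming before the data were seen, included C1qa, a complement gene, which stood at 1801 and 200 CPM, Spp1 at 3045 and 912, Mrc1 at 331 and 124, Trem2 at 282 and 89.7 and Arg1 at 9278 and 5388. Genes with higher levels, taken from the ranking limited by free RNA that was added after, included Plac8 at 530 and 2530, Hp at 71.9 and 354 and Ifitm6 at 38.5 and 266. All 24 type I interferon response genes were higher (median 1.69, 1.33 to 1.82), with Isg15 at 106 and 424, Ifi27l2a at 389 and 1964, Oas3 at 15.8 and 81.1 and Usp18 at 7.82 and 34.5.

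Macrophage programmes were compared by lists with the class markers left out. Of 15 genes of alternative activation 11 were lower in the PBM library (median -0.93, -1.13 to -0.52), with Mgl2 at 155 and 41.4 CPM and no PBM UMI of Ccl17 or Retnla, which makes them at least 10.3-fold and at least 7.33-fold lower; Ccl24 was higher (187 and 621). Of 12 lipid and scavenger genes of tumour macrophages 9 were lower (median -0.73), with the protease gene Ctsl at 652 and 131 and Cd63 at 410 and 94.9. Their median ranged from -1.05 to -0.44 over all alternatives. The pro-inflammatory list had 8 of 15 genes higher and 6 lower, 1 that could not be placed, and a median of 0.33 (0.01 to 0.44) that took the other sign in thinned cells (-0.05), with the mean of cells (-0.10), at resolutions 0.5 (-0.06) and 2.0 (-0.03) and within the monocyte-led cluster alone (-0.18). Its members went both ways, with Cxcl9, a T cell attracting chemokine, at 696 and 190 CPM, Tnf at 22.2 and 8.62, Il1b at 666 and 1002 and Ptgs2 at 18.1 and 62.1. The alternative activation median was -0.03 in cells thinned to 1000 UMIs each, where 5 of 15 members had no PBM UMI.

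Of 25 interferon-gamma response genes 22 were higher in PBM monocyte/macrophage-like cells (median 0.66), with Irgm2 at 17.0 and 55.2 CPM, Gbp4 at 21.5 and 56.9 and Ciita at 33.8 and 82.8, and all 16 MHC class I genes were higher (median 0.47; H2-K1 1318 and 1780). Both medians were close to 0 within the monocyte-led cluster alone (-0.05 and -0.01), whereas the type I interferon median was 0.86 there. All values within this cluster rest on 83 PBM cells. The MHC class II median was 0.04 (-0.03 to 0.13), and 0.50 with the class from resolution 0.5; H2-Ab1 stood at 3126 and 2816. Chemokine genes that attract T cells and myeloid cells had medians of -0.90 and -0.96, matrix and angiogenesis genes -0.71, with Timp2 at 253 and 53.5, phagocytosis genes -0.32, complement genes -0.24, TGF-beta genes -0.14, suppressor programme genes 0.16, NF-kB genes 0.25 and costimulatory ligand genes 0.33, against 0.20 over all genes. The lowest and highest of these over all alternatives were -1.99 and -0.39 for T cell chemokines, -1.27 and -0.51 for myeloid chemokines, -1.18 and -0.27 for matrix and -0.72 and -0.10 for phagocytosis genes. They were -0.72 and 0.05 for complement, and -0.54 and -0.04 for TGF-beta genes, and -0.46 and 0.42 for suppressor, -0.32 and 0.44 for NF-kB and -0.04 and 0.56 for costimulatory ligand genes. Among these lists the chemokine and matrix medians lay below the ranges of matched random lists, and the others inside theirs. Glycolysis (-0.81), hypoxia (-0.71), cholesterol synthesis (-1.43), NRF2 (-0.35), S phase (-1.17) and G2 and M phase (-1.71) medians were lower. Heat shock was at -0.06, immediate early genes at 0.18, close to the median of all genes (0.20), and apoptosis genes at 0.32. The last 2 ranged from -0.37 to 0.41 and from -0.40 to 0.33 over all alternatives. Heat shock ranged from -0.41 to 0.04, NRF2 from -0.53 to -0.16, hypoxia from -1.03 to -0.51 and glycolysis from -1.11 to -0.43. In thinned cells the floor of 3 counts is 17.0 CPM in the PBM library, above the control level of 9 of 19 S phase and 11 of 23 G2 and M phase genes that had no PBM UMI, so the medians of 0.10 and 0.25 there are set by the floor; without those genes they were -0.48 and -0.50. Within the monocyte-led cluster alone the S phase median was -0.16 (-0.57 to 0.42), that of the G2 and M phases -0.26 (-0.44 to 0.59), cholesterol synthesis -0.69 and glycolysis -0.43. Mki67 rested on 1 PBM UMI (log2 -4.55, -9.86 to -2.07).

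Cd274, the gene of the checkpoint ligand PD-L1, stood at 78.5 and 93.1 CPM in monocyte/macrophage-like cells (log2 0.25, -0.17 to 0.63), Nos2 at 88.2 and 98.3 (-0.25 to 0.53), Tgfb1 at 107 and 133 (-0.03 to 0.64) and Hmox1 at 175 and 157 (-0.47 to 0.14), differences that were not detectable at this depth. Il10 had 162 control UMIs and 1 PBM UMI (log2 -0.86, -6.17 to 1.64). Vegfa stood at 69.8 and 22.4 CPM, and Cxcl10 at 192 and 241, with a ratio below 0 in thinned cells (-0.51) and with the mean of cells (-0.15). By rank, the control side also held Hist1h2bc and Gzmc, both with no PBM UMI (at least 11.6-fold and at least 14.2-fold lower; free RNA could supply all of Gzmc), Mt2 (263 and 25.9), Zfhx3, Pdgfa, Serf1, Fdps, Cd81 (143 and 25.9) and Rgs1 (207 and 37.9), and Rragc under the 50% limit. The PBM side held Fcmr, Cd79a, Ly6d, Ms4a1, Cd79b, Bank1, Scd1, Id3, Tcf7 and Cd8b1, of which free RNA could supply 56.988% or more. Under 50% it held genes such as Ifitm6, Oas3, Ifi27l2a, Dusp2 (19.6 and 96.6), Hp, Plac8, Rasgrp2 (25.9 and 119), Tspan13 (19.5 and 84.5) and Ifit1 (13.2 and 56.9). Free RNA was estimated at 12.7% of the library level in control and 23.8% in PBM cells of this class.

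Across the classes, the type I interferon list was higher in the PBM library in all 4. In T-like cells all 24 members were higher (median 1.04, 0.98 to 1.18), above every one of 10000 random lists matched on expression, with Usp18, a regulator of interferon signalling, at 7.199 and 28.1 CPM, Oasl1 at 1.93 and 17.5, Oasl2 at 3.64 and 14.3, Oas2 at 0.742 and 6.50 and Isg15 at 73.3 and 139. The T-like median was 0.52 without the Ifng-led cluster, with 18 of 24 members higher, and 0.14 with the class from resolution 0.5, so its size depends on the T cell states compared. In B-like cells it was 0.62 within the single cluster that held most control cells. Among T cells gated on Cd8a or Cd8b1 and on Cd4 it was 1.38 and 0.97. A place above every random list was not particular to this list, since lists about genes of other classes reached it too. Their medians included 1.05 for MHC class II in T-like cells and 1.58 in NK-like cells. In monocyte/macrophage-like cells memory and stem-like genes had 2.13 and T cell receptor signalling genes 2.06. Other such lists were lower, among them complement genes in T-like cells (-5.4).

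Transcripts encoded by the mitochondrial genome were lower in the PBM library in every class compared, with medians of -1.86 in T-like, -2.04 in B-like, -1.22 in NK-like and -0.42 in monocyte/macrophage-like cells. The size varied in the last 2: NK-like cells had -2.01 when thinned, -1.79 with the mean of cells' CPM and -0.85 with free RNA subtracted. Monocyte/macrophage-like cells had -1.05 within the monocyte-led cluster alone, -0.74 when thinned, -0.69 with the mean of cells' CPM and -0.12 with free RNA subtracted. In that class as a whole 9 of 12 members were lower, 2 were higher and 1 could not be placed. The gene of a cytochrome c oxidase subunit, mt-Co1, stood at 403 and 79.0 CPM in T-like, 540 and 95.3 in B-like, 300.2 and 97.9 in NK-like and 995 and 745 in monocyte/macrophage-like cells. Nuclear genes of oxidative phosphorylation did not follow, with medians of -0.24, -0.05, 0.01 and -0.10 in the same order, and nuclear cytochrome c oxidase subunits had -0.65, -0.05, -0.06 and -0.02. The highest medians over all alternatives were 0.07, 0.52, 0.17 and -0.001 for the former and -0.35, 0.40, 0.08 and 0.13 for the latter. The lowest were -0.29, -0.11, -0.18 and -0.21, and -0.65, -0.07, -0.24 and -0.13. Mitochondrial UMIs made up 0.255% of the control and 0.0409% of the PBM library. The median share per barcode was 0.1435% and 0.0167%, so few mitochondrial UMIs stood behind each cell in either library. TMM factors would raise every log2 ratio by 0.31 in T-like and 0.28 in B-like cells and shift it by -0.18 and -0.05 in NK-like and monocyte/macrophage-like cells; the T cell receptor signalling and oxidative phosphorylation medians of T-like cells then stood at 0.13 and 0.07.

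**Figure D3:**
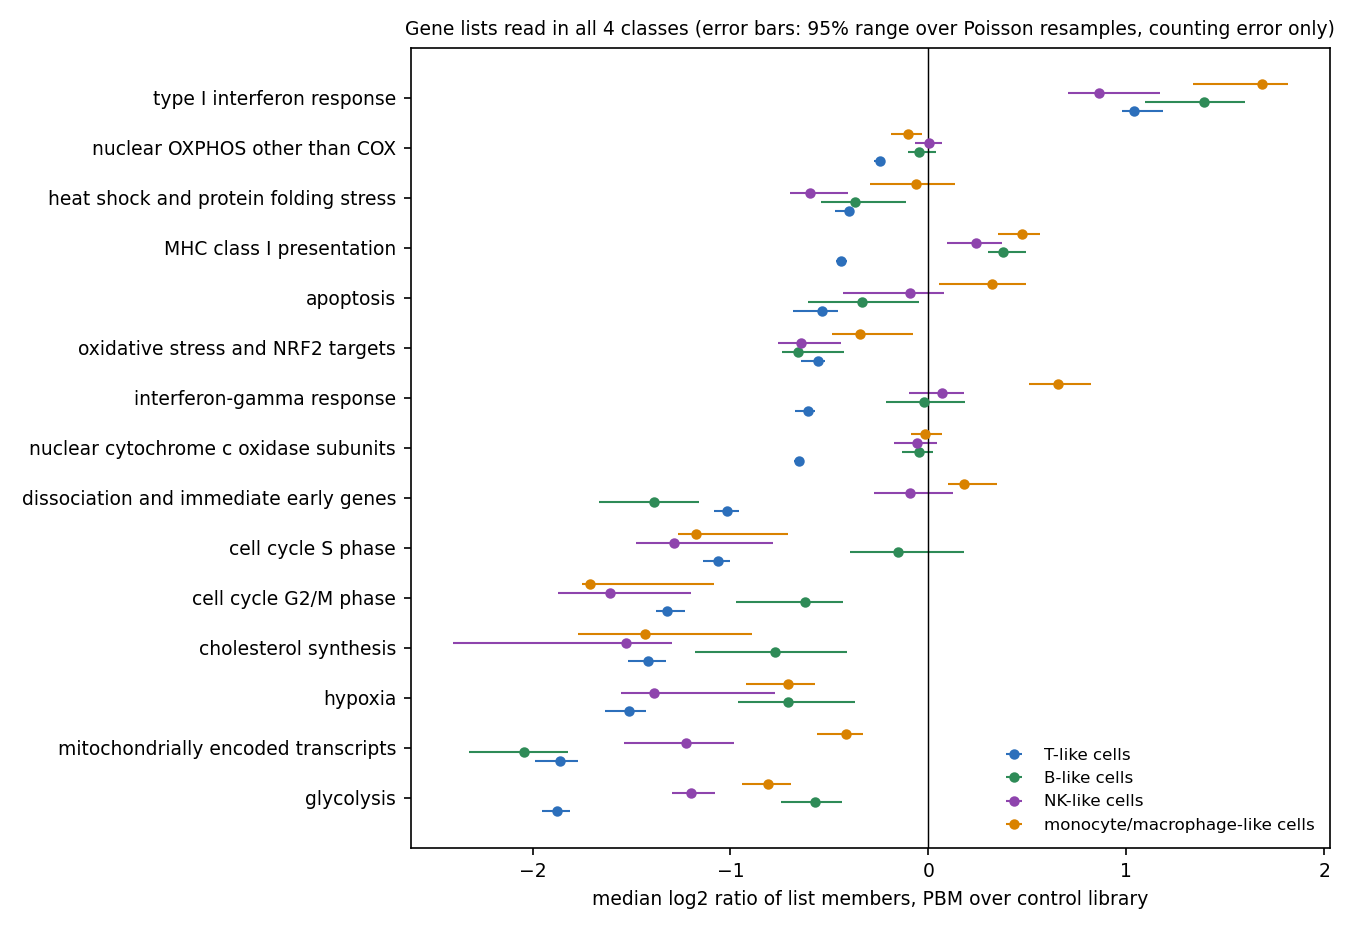
Median log2 ratio, PBM over control library (horizontal axis), of the gene lists read in all 4 cell classes (colours), with 95% ranges over Poisson resamples that cover counting error only. The type I interferon medians lie between 0.86 and 1.69 and the mitochondrially encoded medians between -2.04 and -0.42; medians near 0 take the other sign under some alternatives, among them nuclear oxidative phosphorylation in T-like cells.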

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

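Tests chosen after the data were seen are those with free RNA subtracted, with T cells gated on Cd8a or Cd8b1 or on Cd4, within the monocyte-led cluster alone, without the Sparc-led and low-count clusters, with unnamed clusters given to their leading class, with the Ly6c2-led cluster added to T-like cells or the Ifng-led one left out, and within the B-like cluster led by Igkc alone; the results treated as main ones here were also picked then. A minimum of 1000 UMIs per cell removed no cell, so it gives no value. A value counts as moved when it left the 95% interval of the value reported. It counts as turned when the reported interval also excluded 0 and the sign changed. Where no cause is given below, the cause was not tested.

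Of 893 values that the described list medians took under alternatives, 61 had the other sign, in 30 of 84 pairs of a list and a class; 23 of them, in 16 pairs, count as turned. The other sign was taken by 9 of 84 medians with TMM factors, 9 in thinned cells, 9 with free RNA subtracted, 8 with the mean of cells' CPM, 3 each with doublets kept and at resolutions 0.5 and 2.0, 1 with members of at least 100 UMIs and none with members of at least 1. In size, 71 of the 84 medians changed sign or by over 1.5 times under at least 1 alternative, a limit set after the data were seen and passed easily by medians near 0: 13 of 23 in T-like, 17 of 17 in B-like, 14 of 16 in NK-like and 27 of 28 in monocyte/macrophage-like cells. The other sign was taken by 7 of 17 medians within the Igkc-led cluster and 9 of 28 within the monocyte-led one. Of the gene log2 ratios, 3 of 232 had the other sign with TMM factors (2 turned), 4 of 232 with the mean of cells' CPM (1 turned), 7 of 231 in thinned cells (2 turned), 5 of 220 with free RNA subtracted (2 turned) and none of 173 with doublets kept or of 53 with the Ly6c2-led cluster. The shares of B-like, T-like, NK-like, monocyte/macrophage-like, dendritic-like and neutrophil-like cells kept their direction under every alternative run for them.

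Differences in share, PBM minus control, moved as follows, in percentage points. With doublets kept, B-like cells had 43.7, sub-clusters of CD8 type -68.16, naive-like ones 43.717 and conventional CD4 ones 0.0, since no sub-cluster then met that name. Resolution 0.5 gave 45.9 for T-like and -46.42 for monocyte/macrophage-like cells, -65.69 for CD8 and 39.4 for naive-like sub-clusters. Resolution 2.0 gave -3.35 for dendritic-like cells, -57.13 for CD8, 27.8 for naive-like and -15.05 for regulatory sub-clusters, and the other sign for conventional CD4 (-6.70) and monocyte (-2.47) sub-clusters. Each library clustered on its own gave 33.989 for B-like, 23.6 for T-like and -29.32 for monocyte/macrophage-like cells. Thinned cells gave 30.2 for T-like cells, unnamed clusters given to their leading class 29.6, and leaving out the Sparc-led and low-count clusters, which removes mainly control cells, 24.8 for T-like, -50.77 for monocyte/macrophage-like and -12.10 for NK-like cells. T cells split by UMIs gave the other sign for CD8 (4.47) and conventional CD4 (-3.20) and -9.39 for regulatory cells. The split counts receptor genes, while the sub-cluster names also rest on effector genes. Background alone could give the sign for CD8, since the same gate took 2.91% of control and 8.97% of PBM B-like cells.

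TMM factors add 1 constant to every log2 ratio of a class. In T-like cells they gave cytotoxicity -3.47, exhaustion -3.77, memory and stem-like 2.13, type I interferon 1.35 and mitochondrially encoded transcripts -1.55, and the other sign for T cell receptor signalling (0.13), nuclear oxidative phosphorylation (0.065) and H2-K1 (0.072; 0.25 in CD8-gated cells). In B-like cells type I interferon was 1.68 and mitochondrial transcripts -1.76, and in NK-like cells cytotoxicity was -0.78 and type I interferon 0.68.

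With the class from resolution 0.5 the T-like medians were -1.83 for cytotoxicity, -3.14 for exhaustion, 1.27 for memory and 0.14 for type I interferon. Leaving out the Ifng-led cluster alone gave -2.01, -3.57, 1.35 and 0.52 in that order, and -1.75 for mitochondrial transcripts; the class from resolution 0.5 also took in cells without a class at resolution 1.0, and what they add was not tested apart. T cells gated on Cd8a or Cd8b1 had -4.85 for cytotoxicity, -4.41 for exhaustion, 1.38 for type I interferon and -1.63 for mitochondrial transcripts, and T cells gated on Cd4 had -2.41, -3.13, 0.97 and -1.58 in that order and 1.53 for memory. Doublets kept gave -3.56 for cytotoxicity, -3.71 for exhaustion, 1.58 for memory and 0.94 for type I interferon. The Ly6c2-led cluster added gave -3.71 for exhaustion, 1.56 for memory and 0.96 for type I interferon. The mean of cells' CPM gave -3.52 for cytotoxicity, 1.61 for memory, 0.81 for type I interferon and -2.06 for mitochondrial transcripts. Members with at least 100 UMIs gave -3.57 for cytotoxicity and 0.95 for type I interferon. Thinned cells gave 1.55 for memory and 0.87 for type I interferon. Free RNA subtracted gave -1.74 for mitochondrial transcripts and, in CD8-gated cells, the other sign for Cd79a (-1.60).

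In B-like cells thinning gave 0.94 for type I interferon (1.31 without 4 genes that the floor decides) and -2.43 for mitochondrial transcripts, and the other sign for heat shock (0.14), apoptosis (0.033) and Oas3 (-0.24, which had 1 control UMI before thinning). Free RNA subtracted turned glycolysis to 0.055. Within the Igkc-led cluster type I interferon was 0.62 and mitochondrial transcripts were at -3.10, and MHC class II (-0.80), heat shock (0.54), apoptosis (0.52) and G2 and M phase genes (1.55) turned. In NK-like cells free RNA subtracted gave -0.44 for cytotoxicity and turned Cd79b to -0.18. Type I interferon there was 0.53 with the mean of cells' CPM and 0.51 in thinned cells.

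Within the monocyte-led cluster of monocyte/macrophage-like cells alone, which removes most control macrophages, type I interferon was 0.86, MHC class II 0.43 and alternative activation -0.47. Turned there were interferon-gamma response (-0.048), MHC class I (-0.013), costimulatory ligands (-0.035), pro-inflammatory (-0.18), immediate early (-0.37) and apoptosis genes (-0.40), and the suppressor programme (-0.46), NF-kB (-0.32) and nuclear cytochrome c oxidase genes (0.09), whose reported intervals include 0, had the other sign. The mean of cells' CPM gave -0.055 for MHC class II and -0.48 for alternative activation, and the other sign for pro-inflammatory (-0.10) and apoptosis genes (-0.043) and Cxcl10 (-0.15). Thinning gave -0.034 for alternative activation and the other sign for pro-inflammatory (-0.047), S phase (0.10) and G2 and M phase genes (0.25) and Cxcl10 (-0.51); the floor of 3 counts, 17.0 CPM in these PBM cells, sets the cell cycle signs, and without the genes it decides the medians were -0.48 and -0.50. Resolution 0.5 gave 0.50 for MHC class II and turned pro-inflammatory genes to -0.06. Resolution 2.0 turned them to -0.033 and gave -1.245 for alternative activation. Free RNA subtracted gave 1.86 for type I interferon, -0.036 for MHC class II, 0.60 for pro-inflammatory genes, and the other sign for complement genes (0.049).

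Among the classes, depth limits these values most where few cells were kept. These are 206 control B-like, 197 PBM NK-like and 176 PBM monocyte/macrophage-like cells, in which 1 UMI decides single genes. The clusters read alone held fewer still. The monocyte-led cluster had 83 PBM cells with 276419 UMIs, and the Igkc-led cluster had 136 control cells. The 83 cells lie below the minimum set for comparing classes, so medians within the monocyte-led cluster are limited by depth as well. Thinning makes the depth per cell equal but not the summed depth, 5100000 UMIs against 176000 in monocyte/macrophage-like cells. It moved 126 of 231 gene ratios that did not turn.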

Other observations

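The cells re-clustered as dendritic, 467 in the control and 98 in the PBM library, are the dendritic-like cells (157 and 4) and a cluster led by Cd209a, Clec10a and Flt3 that met no class (310 and 94), as its markers were split between dendritic and plasmacytoid dendritic cells. They were too few for gene levels. Sub-clusters of the mature regulatory type held 33.2% of these control cells (28.9 to 37.7) and 4.08% of these PBM cells (1.12 to 10.1). Sub-clusters of cDC1 type held 19.1% and 6.12%, of cDC2 type 14.1% and 7.14%, and of plasmacytoid type 15.2% and 32.7%, while 18.4% and 50.0% met no subtype. These names moved with the settings: at resolution 0.5 no sub-cluster was of cDC1 type, cDC2 ones held 29.6% and 11.2% and plasmacytoid ones 8.57% and 31.6%, and with doublets kept cDC2 ones held 31.4% and 10.7%. A cluster of B-like cells led by Ifit3 and Oasl1 held 1 control and 387 PBM cells, and a T-like cluster led by Ifit1, Ifit3 and Rsad2 held 5 and 115.

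Of the tests below, only that of the interferon-led clusters was written before its result was seen, and all the others were chosen after. The first pattern is the replacement of myeloid and effector cells by B-like and naive-like T-like cells. Loss of myeloid cells alone, if it left T cell states as they were, would not give the change within T-like cells. There the cluster led by Ifng and Pdcd1 held 50.7% of control and 0.277% of PBM T-like cells. That change is part of the pattern itself, so it is no separate test. Whether a loss of myeloid cells would alter T cell states was not tested. A candidate explanation is that lymphoid tissue, such as a draining node, came into the PBM pool beside unchanged tumour cells. Dilution alone would leave every monocyte/macrophage-like cluster the same percentage of its control share. They kept 1.91%, 1.74% and, in the monocyte-led one, 8.47% (6.67 to 10.6), the highest 4.86 times the lowest with intervals apart. Since such tissue could bring monocytes of its own, this does not decide. Among other clusters the Ifng-led one kept 1.31%, the dendritic-like one 2.17%, the NK-like one 12.6% and the neutrophil-like one 14.2%. The Sparc-led one kept 0.49% (0.20 to 1.01), lower than all of these, but a CD45 gate is meant to leave such cells out. Lymphoid tissue in the pool and photobiomodulation cannot be told apart with 1 library per group and no node, spleen or blood library analysed here. A library put under the wrong label, which would change what every PBM value means, was not tested and stays open too.

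The second pattern is the higher type I interferon list in all 4 classes. In T-like, NK-like and monocyte/macrophage-like cells some lists about genes of other classes were as high. Free RNA at its estimated level is argued against. It could supply a median of 15.6% of the level of the interferon genes in PBM T-like cells. Their median after subtraction was 1.09. For genes expressed alike in most classes such a share comes close to the estimate itself, 17.2% in these cells. Both values therefore hold only as far as that estimate does. A few interferon-led clusters alone are argued against as well: without them the T-like median was 0.96, against -0.19 for all genes. The mix of cell states stays open as part of it. The T-like median was 0.52 without the Ifng-led cluster and 0.14 with the class from resolution 0.5. The B-like one was 0.62 within the Igkc-led cluster, and the monocyte-led cluster alone had 0.86. NK-like cells, in 1 cluster, had 0.86, but 0.53 with the mean of cells' CPM and 0.51 when thinned. That cluster does not hold cell state constant, since levels of several granzymes and of cell cycle genes differed within it. Photobiomodulation, the site the cells came from and the library stay open and untested.

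The third pattern is the lower level of mitochondrially encoded transcripts. They were scarce in both libraries, at 0.255% of control and 0.0409% of PBM UMIs. A different mix of cell classes is argued against by the median of -1.86 within T-like cells and -2.04 within B-like cells. These classes lay in different clusters in the 2 libraries, so the medians do not exclude a different mix of cell states. Over all alternatives, some of which changed the clusters compared, they ranged from -2.06 to -1.55 in T-like and from -3.10 to -1.76 in B-like cells. Lower respiratory chain genes as a whole are argued against as the cause of a drop of that size. Nuclear oxidative phosphorylation genes had a median of -0.243 in T-like cells and -0.05 in B-like cells. In T-like cells 38 of 40 of these genes were lower, but so were most genes of that class. Their median lay close to that of all genes (-0.19) and inside the range of matched random lists (-0.45 to -0.07). Nuclear cytochrome c oxidase subunits had -0.65 in T-like cells with 12 of 14 lower, just below their range (-0.62 to 0.18). A smaller part therefore stays open in T-like cells, resting on these subunits. A difference in cell handling or library preparation could give this pattern, and so could the treatment, and neither was tested, since each is bound to the group.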
